A study of Homo sapiens with 27 samples.

How the data were processed

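Poly(A) RNA was sequenced from HBL1 cells, a human diffuse large B-cell lymphoma line of the activated B-cell-like type, that carried Cas9 and were collected 6 days after infection with a single guide RNA. The labels list 20 expression samples, 4 with control guides (sgROSA), 10 with guides against NFKBIZ (sgNFKBIZ) and 6 with guides against POU2F2 (sgPOU2F2), as 2 numbered samples for each guide. One deposited table was used per guide, and the labels of both samples of a guide name the same table; whether a table pools both is not stated. The replicate here is therefore the guide, with 2 sgROSA, 5 sgNFKBIZ and 3 sgPOU2F2 libraries. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which includes differences between guides. The 7 chromatin immunoprecipitation samples of the series were not analysed here.

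The authors quantified reads against Ensembl transcripts with kallisto 0.46.1 on build GRCh38, per the submitters' processing notes, which also name DESeq2 1.40.2. The index and the bias options are not given in the sources used here. Each deposited table lists 184203 transcripts with an estimated count per transcript, which is not normalized and need not be whole, because a read that fits several transcripts is divided among them. TPM, a column per the file headers, is by definition the count divided by effective length and scaled to a common sum. The deposited effective lengths, another column per the file headers, served only as an offset in an alternative.

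The files do not pair transcripts with genes, and 0 of the transcript identifiers matched the gene tables used here. The groups, contrasts, test, filter, naming rule and first alternatives were chosen before the data were examined, for sums per gene. The tests were run per transcript instead. The levels of NFKBIZ and POU2F2 mRNA, which would check the guides, and 34 gene lists were therefore not analysed here. Transcripts of one gene share sequence, so an estimated count can move between them with no change in the gene.

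Estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15), all 10 libraries in one fit with a coefficient per group, and Benjamini-Hochberg adjustment at 0.05. This left 83260 transcripts. After it was seen that few of them passed, a second fit was added on whole-count transcripts, those whose estimated counts were exactly whole as printed in all 10 libraries, so that no sharing of reads was visible. Of 41945 such transcripts, most of them at 0, 6 reached 100000 counts, where the files print no decimals, and were left out, and 467 passed the filter. They held 2.18% to 2.66% of a library's counts, and their filter and TMM factors were computed among themselves. Filters at a mean estimated count above 50 and above 500 had been tried at the same time and are given with the alternatives.

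Library totals ran from 11776900 to 30917000 estimated counts. The biological coefficient of variation was 0.817 over all transcripts and 0.134 over whole-count transcripts. The test was tried on 20 simulated sets of counts with the real means, dispersions and totals, after 2 single runs had given different recoveries. With 200 of the transcripts changed, the fit over all transcripts recovered a mean of 0.113% of 2-fold and 4.98% (0 to 13.6%) of 4-fold changes for sgNFKBIZ against sgROSA, and 0.111% and 3.11% (0 to 11.1%) for sgPOU2F2 against sgROSA. With 40 changed, the fit over whole-count transcripts recovered a mean of 70.1% (52.6% to 88.2%) of 2-fold and 98.3% of 4-fold changes for sgNFKBIZ, and 67.5% (52.6% to 82.4%) and 98.0% for sgPOU2F2. Of all its calls, 4.71% for sgNFKBIZ and 5.09% for sgPOU2F2 were unchanged transcripts, and over all transcripts these shares were 4.35% and 1.75%. The changed shares differed, 200 of 83260 and 40 of 467, so the recoveries of the 2 fits are not directly comparable.

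Transcripts to be named were those with an adjusted p under 0.05, an average log2 CPM of at least 2 and every library of one group above every library of the other, ranked by log2 fold change; for transcripts that passed in both contrasts with control, the rank was by the smaller of the 2 changes. NFKBIZ, POU2F2, POU2AF1 and members of gene lists were also to be named and were not analysed here. Because no gene names could be attached, only 4 identifiers are printed. They rank first among whole-count transcripts, in each direction, in sgPOU2F2 against sgROSA and in the overlap of both contrasts, and these places in the ranking were chosen after the values were seen. CPM values of single transcripts refer to a library's total over the 83260 tested transcripts, with their TMM factors. The level of log2 CPM refers to the full library total without TMM factors, while fold changes come from the fit over whole-count transcripts.

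Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter (CPM of at least 1 in every library of a group), an effective length offset, limma 3.58.1 on log2(TPM + 1), a test against a fold change of 1.2, fits of only the 2 groups compared, and fits without each library. The same alternatives on whole-count transcripts, the TMM factors of all transcripts, a laxer filter of 1 CPM of whole-count reads, the removal of a trend with transcript length and fits that gave each target another control library were added after seeing the data. To measure what shared control libraries give with no effect, with the control libraries shared or split, unchanged groups were simulated 20 times for all transcripts and 100 times for whole-count transcripts. Figures were drawn with matplotlib 3.10.9.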

Results

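The expression data compare HBL1 lymphoma cells in which Cas9 was directed at NFKBIZ, which encodes the nuclear NF-κB cofactor IκBζ, or at POU2F2, which encodes the B-cell transcription factor OCT2, with cells that received control guides. The series title names IκBζ as a coactivator of NF-κB and POU factors, so the design asks which transcripts respond to each target and which respond to both. There were 2 sgROSA, 5 sgNFKBIZ and 3 sgPOU2F2 libraries, each from a different guide. Libraries are named by group and guide. The sgROSA_1 and sgROSA_2 libraries held 24991300 and 25418200 estimated counts. The sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_103, sgNFKBIZ_104 and sgNFKBIZ_106 libraries held 23760700, 26354800, 11776900, 25088300 and 26219600. The sgPOU2F2_5, sgPOU2F2_8 and sgPOU2F2_9 libraries held 22995400, 30917000 and 27215100. No transcript could be given a gene name, so the depletion of NFKBIZ and POU2F2 mRNA was not checked here and results are described for transcripts.

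Libraries were less alike over all transcripts than over transcripts with no visible sharing of reads. Across transcripts, which are not independent replicates, Pearson's r between pairs of libraries was 0.757 to 0.846 for all tested transcripts and 0.966 to 0.989 for the 467 whole-count transcripts. The first principal component of the whole-count transcripts, 25.9% of the variance, placed the 3 sgPOU2F2 libraries between -7.66 and -6.70 and the other 7 libraries between 2.10 and 4.46.

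**Figure D1:**
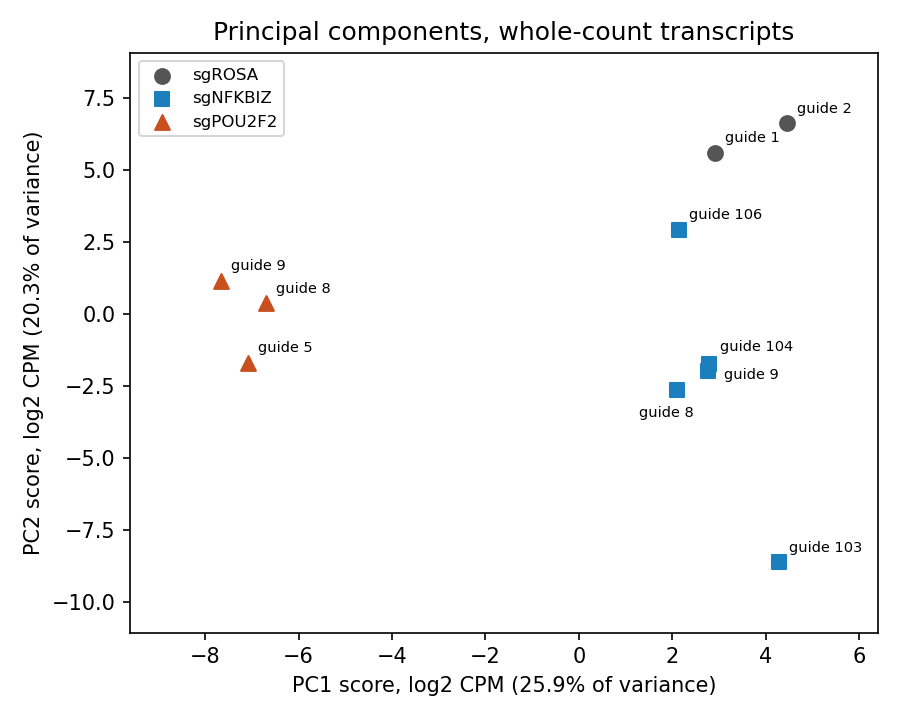
Scores of the 10 libraries on the first (horizontal) and the second (vertical) principal component of log2 CPM over 467 whole-count transcripts, with 1 point per library, shaped and coloured by group and labelled with its guide number. The sgPOU2F2 libraries lie between -7.66 and -6.70 on the first component, and the other libraries lie between 2.10 and 4.46.

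In sgPOU2F2 against sgROSA libraries 34 of the 467 whole-count transcripts differed, 16 upward and 18 downward. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. The median change was 1.33 on the log2 scale among those that rose and -0.83 among those that fell. ENST00000269593.5 rose from 5.43 ± 2.05 CPM (SD, n = 2) to 16.6 ± 3.83 CPM (SD, n = 3), a log2 fold change of 1.69 (SE 0.24, edgeR adjusted p = 0.000238). ENST00000217381.3 fell from 19.5 ± 0.679 CPM (SD, n = 2) to 8.38 ± 0.920 CPM (SD, n = 3), a log2 fold change of -1.14 (SE 0.16, edgeR adjusted p = 0.000238). Both stayed past the threshold in all 21 alternatives, with adjusted p of 2.17e-13 to 0.0166 and 6.93e-08 to 0.0102. These alternatives were all fits over whole-count transcripts. In the fit over all transcripts 0 whole-count transcripts passed, so neither passed there. The groups did not overlap for 36.4% of the whole-count transcripts, where chance gives 20%. Without sgROSA_2 the count was 14.

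Over all 83260 transcripts the same comparison called 32, of which 22 rose and 10 fell, and 6379 had an unadjusted p under 0.05 where 4163 would be expected by chance. This count rested on single libraries and on the tool: it was 313 without sgROSA_1, 10 without sgROSA_2, 1 to 3 without any one of sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_104, sgNFKBIZ_106, sgPOU2F2_5 and sgPOU2F2_9, and 0 without sgPOU2F2_8 in edgeR, with 6103 at an unadjusted p under 0.05. It was 1754 with DESeq2 and 88 with limma.

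In sgNFKBIZ against sgROSA libraries 18 of the whole-count transcripts differed, 6 upward and 12 downward. The median change was 0.96 among those that rose and -0.57 among those that fell. The groups did not overlap for 24.4% of the whole-count transcripts, where chance gives 9.52%, and 107 transcripts had an unadjusted p under 0.05 where 23.4 would be expected. The count depended on single libraries. In edgeR it was 0 without sgROSA_2, with 60 at an unadjusted p under 0.05, and 4 without sgROSA_1. It was 9, 2, 5 and 45 without sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_103 and sgNFKBIZ_106, and 31 and 28 without sgPOU2F2_5 and sgPOU2F2_9. It was 0 with limma on log2(TPM + 1), with 111 at an unadjusted p under 0.05, and 38 with DESeq2.

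Over all transcripts sgNFKBIZ libraries had 7773 at an unadjusted p under 0.05 and differed from control in 7, of which 6 rose and 1 fell. The 6 had a median fitted log2 change of 9.31, and in 2 of the 7 every library of 1 group was at 0. Of the 7 calls counted, 0 were whole-count transcripts. The count was 301 without sgROSA_1, 1 without sgNFKBIZ_9, 17 without sgNFKBIZ_106, and 2 and 3 without sgPOU2F2_5 and sgPOU2F2_9. In edgeR it was 0 without sgNFKBIZ_8, sgNFKBIZ_104 or sgPOU2F2_8, with 6371, 6712 and 7077 at an unadjusted p under 0.05. It was 2450 with DESeq2 and 73 with limma. The transcript that fell (edgeR adjusted p = 0.0389) held 132 and 87.2 estimated counts in the sgROSA libraries and at most 0.740 in each sgNFKBIZ library, under the floor of 3 counts, so its fitted fold change is not given. It lay below the level set for naming and was singled out after its values were seen. Its estimated counts were not all whole, so reads were shared with other transcripts.

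Set directly against each other, sgPOU2F2 and sgNFKBIZ libraries differed in 53 whole-count transcripts, of which 25 were higher and 28 lower with guides against POU2F2. The 2 groups did not overlap for 45 of these 53, and in 3 of the 53 every library of 1 group was at 0. This comparison does not use the control libraries for its fold changes. ENST00000269593.5 was 1.21 higher on the log2 scale in sgPOU2F2 than in sgNFKBIZ libraries (SE 0.17, edgeR adjusted p = 0.000316), where it stood at 7.27 ± 1.52 CPM (SD, n = 5), and its difference between sgNFKBIZ and sgROSA did not pass (log2 fold change 0.49, SE 0.22, edgeR adjusted p = 0.193) and passed in 0 of 21 alternatives (adjusted p 0.0695 to 0.879). ENST00000217381.3 was lower in sgPOU2F2 than in sgNFKBIZ libraries by a log2 fold change of -0.53 (SE 0.14, edgeR adjusted p = 0.0162), a call that held in 16 of 21 alternatives (adjusted p 0.00972 to 0.105) and was lost without sgPOU2F2_5 or sgPOU2F2_9. The groups did not overlap for 14.8% of whole-count transcripts, where chance gives 3.57%. The count was 34 without sgPOU2F2_8 and 24 without sgPOU2F2_9. Over all transcripts 19 passed, 5 higher and 14 lower, and 0 of the 19 were whole-count transcripts. The count was 824 with DESeq2 and 96 with limma. With every library kept, 4290 had an unadjusted p under 0.05 where 4163 would be expected by chance. The groups did not overlap for 4.91% of all transcripts, where chance gives 3.57%. In edgeR 1 passed without sgNFKBIZ_8 and 0 without sgNFKBIZ_9, sgNFKBIZ_104, sgPOU2F2_5, sgPOU2F2_8 or sgPOU2F2_9, with 3189 to 4069 at an unadjusted p under 0.05.

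In both contrasts with control 7 whole-count transcripts passed in the same direction, 3 upward and 4 downward, and 0 in opposite directions. Independent lists of these sizes would share 0.206 upward and 0.463 downward. ENST00000259030.3 rose from 10.3 ± 0.742 CPM (SD, n = 2) in sgROSA to 14.9 ± 2.13 CPM (SD, n = 5) in sgNFKBIZ and 14.9 ± 1.59 CPM (SD, n = 3) in sgPOU2F2 libraries, with log2 fold changes of 0.60 (SE 0.14, edgeR adjusted p = 0.0248) and 0.62 (SE 0.15, edgeR adjusted p = 0.0132). ENST00000421952.3 fell from 15.2 ± 3.57 CPM (SD, n = 2) to 7.60 ± 1.80 CPM (SD, n = 5) and 8.15 ± 0.862 CPM (SD, n = 3), with log2 fold changes of -0.92 (SE 0.19, edgeR adjusted p = 0.0227) and -0.82 (SE 0.21, edgeR adjusted p = 0.0202). ENST00000217381.3 also fell with guides against NFKBIZ, to 12.2 ± 2.03 CPM (SD, n = 5), a log2 fold change of -0.61 (SE 0.14, edgeR adjusted p = 0.0248).

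The calls of these 3 transcripts depended on single libraries, except that of ENST00000217381.3 in sgPOU2F2 against sgROSA. In the fit over all transcripts 0 whole-count transcripts passed, so these 3 did not pass there in either contrast with control. ENST00000259030.3 passed in 12 of 21 alternatives for sgNFKBIZ (adjusted p 0.00446 to 0.237) and 16 of 21 for sgPOU2F2 (0.00349 to 0.124), with log2 fold changes of 0.50 to 0.70 and 0.52 to 0.70, and both calls were lost without sgROSA_1, without sgROSA_2 and with the TMM factors of all transcripts, the call for sgNFKBIZ also without sgNFKBIZ_8 or sgNFKBIZ_9. ENST00000421952.3 passed in 16 of 21 for sgNFKBIZ (0.000170 to 0.291) and 15 of 21 for sgPOU2F2 (0.00559 to 0.311), with log2 fold changes of -1.16 to -0.56 and -1.07 to -0.48, and both calls were lost without sgROSA_2, the former also without sgNFKBIZ_9 and the latter without sgPOU2F2_8 or sgPOU2F2_9. ENST00000217381.3 passed in 12 of 21 for sgNFKBIZ (0.00366 to 0.237), with log2 fold changes of -0.70 to -0.40, and the call was lost without sgROSA_1, sgROSA_2, sgNFKBIZ_8, sgNFKBIZ_9 or sgNFKBIZ_103. The shared count was 2 without sgROSA_1 and 0 without sgROSA_2 in edgeR, with 60 and 70 transcripts at an unadjusted p under 0.05 in the contrasts of sgNFKBIZ and sgPOU2F2. It was 3, 1, 4, 4 and 14 without sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_103, sgNFKBIZ_104 and sgNFKBIZ_106, and 13 with DESeq2.

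The 2 contrasts use the same control libraries, so part of this excess may come from them. With a different control library for each target, edgeR called few or no whole-count transcripts for sgNFKBIZ. A count of shared calls therefore could not test the overlap. With sgROSA_1 for sgNFKBIZ and sgROSA_2 for sgPOU2F2, 57 and 109 had an unadjusted p under 0.05 and 0 and 35 passed. With the controls exchanged, 108 and 74 had an unadjusted p under 0.05 and 3 and 8 passed. The covariance of the log2 fold changes was 0.120 under the first assignment, above the -0.059 to 0.108 of simulated unchanged groups, and -0.036 under the second, inside the simulated -0.045 to 0.094. Since the covariance differed between the 2 assignments, a shared response was not separated from the shared controls among whole-count transcripts. Each of these contrasts rests on 1 control library, assumed to vary like the other groups, and DESeq2 and limma were not run on them. With both control libraries in both contrasts, the log2 fold changes across whole-count transcripts had a Pearson's r of 0.455 and a covariance of 0.213. Unchanged groups simulated against shared controls gave an r of 0.374 to 0.816 and a covariance of 0.048 to 0.189 (mean 0.100), with 0 shared calls in any of 100 simulations. The observed covariance was 0.113 above the simulated mean, while the observed r lay inside the simulated range. Over all transcripts 6 rose in both contrasts and 0 fell in both in edgeR (835 and 152 with DESeq2). These 6 were all the rises for sgNFKBIZ, with a median fitted log2 change of 9.31 there, and 0 were whole-count transcripts. Reads moved between transcripts could give such changes and were not separated from a response. Over all transcripts r was 0.737 (simulated 0.652 to 0.666, mean 0.659) and the covariance 2.87 (simulated 1.95 to 2.03, mean 1.99). With a different control library for each target, the covariance over all transcripts was 1.09 under both assignments. Simulated unchanged groups gave 0.454 to 0.557 and 0.453 to 0.583 (means 0.497). In all these simulations each transcript was drawn on its own, with no reads moved between transcripts and no difference shared across a library. Splitting the controls also cannot remove a difference common to both control libraries. The excess over all transcripts therefore does not separate a shared response from these sources. The 6 shared calls over all transcripts became 0 to 3 without any one of sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_104, sgNFKBIZ_106 and the sgPOU2F2 libraries.

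The response of single guides was taken against a control library left out, over transcripts called in a fit without both, and averaged over both controls. Among whole-count transcripts 98.1%, 88.5% and 98.3% moved in the direction of the call for sgPOU2F2_5, sgPOU2F2_8 and sgPOU2F2_9, as means over small sets. With sgROSA_1 left out the shares were 96.3%, 100% and 96.7%, and with sgROSA_2 left out 100%, 76.9% and 100%. The median log2 change in the direction of the call was 1.02 for sgPOU2F2_5, 0.82 for sgPOU2F2_8 and 0.94 for sgPOU2F2_9. It was 0.46 for sgNFKBIZ_106, the mean of 0.22 over 31 transcripts with sgROSA_1 left out and 0.70 over 4 with sgROSA_2 left out, and the other sgNFKBIZ guides had no value because a fit without them called none. Over the 200 transcripts of smallest p, most of which were not called, every guide had a value. It was 0.32, 0.25 and 0.28 for sgPOU2F2_5, sgPOU2F2_8 and sgPOU2F2_9, and 0.30, 0.28, 0.38, 0.24 and 0.13 for sgNFKBIZ_8, sgNFKBIZ_9, sgNFKBIZ_103, sgNFKBIZ_104 and sgNFKBIZ_106. The shares that moved in the direction of the fit were 71.75%, 71.5% and 74.5% for the sgPOU2F2 guides and 67.25% to 75% for the sgNFKBIZ guides.

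**Figure D2:**
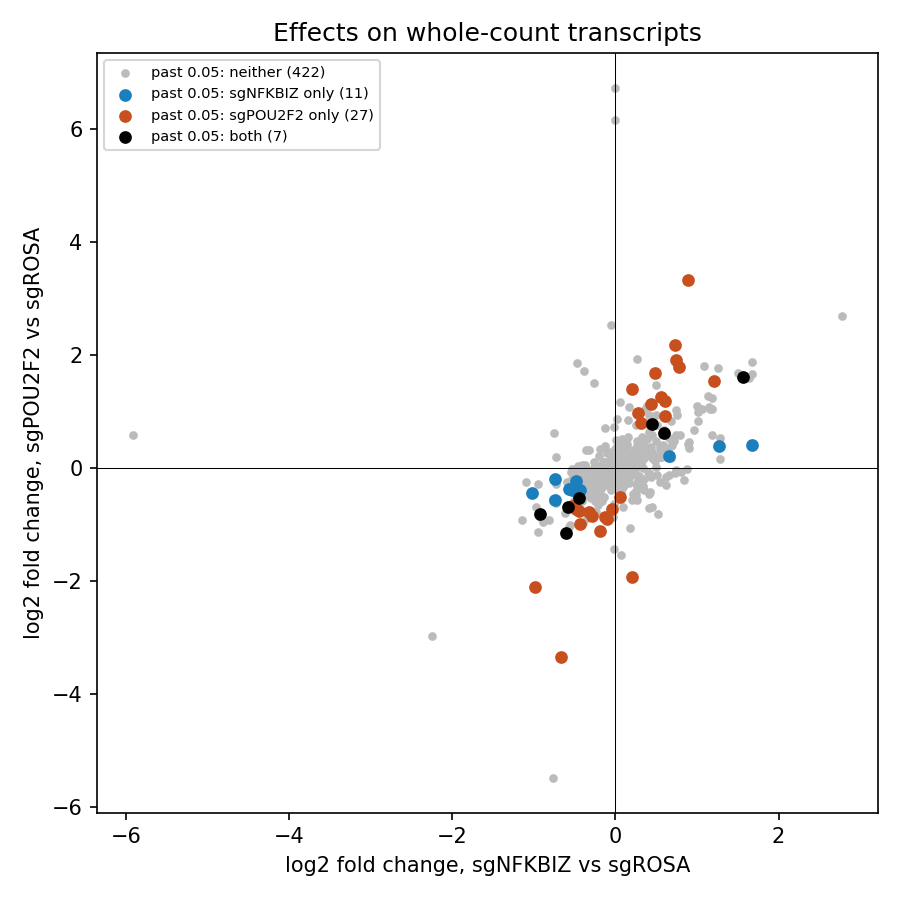
Log2 fold change of each of 467 whole-count transcripts with guides against NFKBIZ (horizontal) and against POU2F2 (vertical), both relative to the same 2 sgROSA libraries, with 1 point per transcript, coloured by the contrast in which its edgeR adjusted p was under 0.05. The 7 black points passed in both, 3 in the upper right and 4 in the lower left quadrant.

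**Figure D3:**
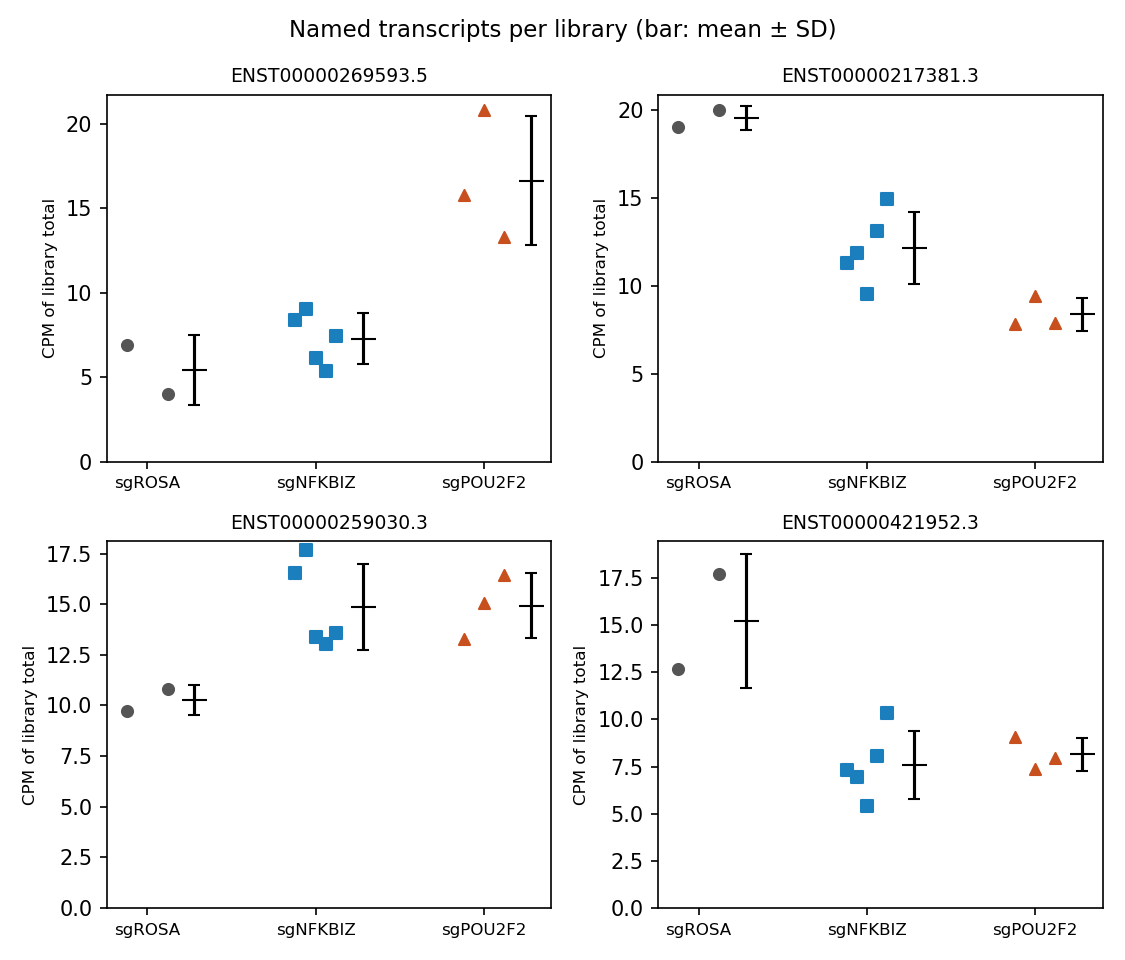
CPM for the 4 named transcripts, with 1 point per library (2 sgROSA, 5 sgNFKBIZ, 3 sgPOU2F2) and the mean ± SD of each group to its right. The library total named on the axes is the total over all tested transcripts. Vertical axes start at 0. ENST00000269593.5 averaged 16.6 CPM in sgPOU2F2 against 5.43 CPM in sgROSA libraries, and ENST00000217381.3 averaged 8.38 against 19.5 CPM.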

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

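The test of depth in this part was chosen after the pattern was seen. Only the sgNFKBIZ group was screened for outlying libraries, on 15 measures, by a gap above 0.71 of the group's range. On 6 of them the library sgNFKBIZ_103 lay far from the other 4. It held 11776900 estimated counts (11.8 in units of 1e+06), where the next lowest held 23760700. It had 92109 transcripts above 0 (next 100497) and 52913 at 10 counts or more (next 63803). Its mean correlation with the other libraries was 0.764 over all transcripts (next 0.814) and 0.974 over whole-count transcripts (next 0.982). It scored -396.2 on the first principal component of all transcripts, where the other 4 scored 38.9 to 72.5. The measures are related to one another, and chance marks about 1 in 20 groups on a single measure. The sgROSA libraries were not screened, and sgROSA_2 scored 320.7 on the second principal component of all transcripts. The other libraries scored -124 to 105 on that component.

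Low depth is a candidate explanation for sgNFKBIZ_103. When every other library was thinned to the total of sgNFKBIZ_103, its mean correlation was 0.802, below each of the other 9 libraries (at most 0.856), but by less than the range among those 9, the bound set beforehand. When each library was thinned alone and compared with libraries at full depth, it stood at 0.764 against 0.801 to 0.835, below the others by slightly more than their range. Both comparisons placed it lowest, but they fall on different sides of the bound, so depth as the whole cause was not decided, and no biological explanation was tested. Without this library, sgNFKBIZ against sgROSA called 5 whole-count transcripts in place of 18.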

How the results depend on the processing

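All alternatives on whole-count transcripts, and the filters on a mean estimated count, were chosen after seeing the data. Where a count moved, the cause was not tested. Over all transcripts, counts are given for sgNFKBIZ against sgROSA, sgPOU2F2 against sgROSA, sgPOU2F2 against sgNFKBIZ and the overlap, which were 7, 32, 19 and 6. They became 2450, 1754, 824 and 987 with DESeq2, 73, 88, 96 and 42 with limma on log2(TPM + 1), 25, 102, 78 and 22 with the stricter filter, 11, 79, 66 and 10 at a mean estimated count above 50, and 39, 101, 115 and 24 above 500. Without a filter, sgPOU2F2 against sgROSA called 1 and the overlap 1, and against a fold change of 1.2 sgPOU2F2 against sgROSA called 1. With only the 2 groups compared, edgeR called 0 for sgNFKBIZ and 0 for sgPOU2F2 against sgROSA, with 6539 and 5538 at an unadjusted p under 0.05. Leaving out 1 library at a time gave 0 to 301, 0 to 313, 0 to 19 and 0 to 259; where a group kept 1 library, it was assumed to vary like the others. RLE size factors and the effective length offset kept all 4 counts within 1.5 times. Restricting the test to whole-count transcripts gave 18 for sgNFKBIZ against sgROSA, 53 for sgPOU2F2 against sgNFKBIZ and 34 for sgPOU2F2 against sgROSA. In each of these contrasts 0 of the calls over all transcripts were whole-count transcripts, so the 2 fits shared no call.

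Among whole-count transcripts the counts were 18, 34, 53 and 7. The 34 of sgPOU2F2 against sgROSA stayed within 1.5 times under every alternative that kept both control libraries, with 32 to 41 over left-out target libraries. The count fell by more than that where sgROSA_1 was its only control library. Of the 34, 31 were shared with DESeq2 and 24 with limma. sgPOU2F2 against sgNFKBIZ gave 26 against a fold change of 1.2, 19 with 1 CPM of whole-count reads as the filter and 24 to 53 over left-out libraries. sgNFKBIZ against sgROSA gave 38 with DESeq2, 43 with the stricter filter, 30 with only the 2 groups compared, 32 with the length trend removed, 2 against a fold change of 1.2, 0 with limma, 0 in edgeR with 1 CPM of whole-count reads (111 and 195 at an unadjusted p under 0.05) and 0 to 45 over left-out libraries. The overlap was 13 with DESeq2, 16 with the stricter filter, 2 without a filter, 0 with limma, 0 with 1 CPM of whole-count reads and 0 to 14 over left-out libraries. Fits with a different control library for each target, added after seeing the data, could not test the overlap by calls. Each contrast rested on 1 control library, and among whole-count transcripts few or none passed for sgNFKBIZ. With the TMM factors of all transcripts, sgNFKBIZ against sgROSA split into 4 up and 15 down, and with the length trend removed into 6 up and 26 down, beside 6 and 12.

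The guide response is the median signed log2 change of a guide, against a control library left out, over transcripts called without both. Over all transcripts it was 0.50 for sgNFKBIZ_103, 3.54 for sgNFKBIZ_106 and 0.51 for sgPOU2F2_5. Very few transcripts carry these means: sgNFKBIZ_103 had -0.07 over 542 transcripts with sgROSA_1 left out and 1.06 over 2 with sgROSA_2 left out, sgNFKBIZ_106 had 0.27 over 213 and 6.81 over 1, and sgPOU2F2_5 had 0.56 over 120 and 0.45 over 3. It moved to 0.043, 0.31 and 0.46 with the 200 transcripts of smallest p and to 0.13, 0.30 and 0.47 with the stricter filter. Over whole-count transcripts it was 0.46 for sgNFKBIZ_106 and 1.02, 0.82 and 0.94 for sgPOU2F2_5, sgPOU2F2_8 and sgPOU2F2_9, which moved to 0.13, 0.32, 0.25 and 0.28 with the 200 transcripts of smallest p, and to 0.25 for sgNFKBIZ_106 with the stricter filter. The other guides had no value, because at least 1 of the fits called none.

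No paired analysis was possible because the tables carry no replicate number. Alternatives for the targeted genes, for the gene lists and for sums per gene were not run, since transcripts could not be assigned to genes. With 200 of 83260 transcripts changed, the fit over all transcripts recovered a mean of 4.98% of simulated 4-fold changes in sgNFKBIZ against sgROSA. How much of this comes from depth, from the spread or from the small changed share was not tested.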

Other observations

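The tests of whole-count transcripts, of a length trend and of transcripts at 0 in the controls were chosen after those patterns were seen; the division of the libraries was planned. The separation of sgPOU2F2 from sgNFKBIZ libraries was set against other divisions of these 8 libraries into 5 and 3, with the control libraries kept in the fit. For whole-count transcripts 1 of 56 splits, the real one, gave as many calls, 53 against at most 12 in any other. For all transcripts it was again 1 of 56, 19 calls against at most 3. In both sets the share was under the bound set beforehand, and it is the smallest that 56 splits can give. This argues against a chance division for the whole-count transcripts. For all transcripts the 19 calls became 0 without sgNFKBIZ_9, sgNFKBIZ_104 or any one sgPOU2F2 library. There 4290 had an unadjusted p under 0.05 where 4163 would be expected, so a chance division is not excluded for that set.

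A trend with transcript length was weighed for the calls among whole-count transcripts. With a smooth trend removed from each library, sgPOU2F2 against sgROSA called 50 in place of 34, and all 34 were among them, which argues against the trend as the source of these calls. For sgNFKBIZ against sgROSA 32 were called in place of 18, of which 17 were shared. The rise went beyond the bound of 1.5 times set beforehand, which had not foreseen a rise, and the shared calls, read afterwards, argue against the trend as the whole source of these 18. A response to each target remains a hypothesis, since batches are not given in the labels.

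In 11 transcripts the estimated count was 0 in both sgROSA libraries and at least 1 CPM in the 8 others, a pattern that a response to both targets could give. Any pair of libraries was weighed as a source: 4 of the 45 pairs had as many such transcripts (at most 39), above the 5% set beforehand for this explanation, and the 3 besides the control pair all hold sgNFKBIZ_103. Of the 36 pairs without that library 1, the control pair, had as many. That library was left out because the competing pairs hold it, so this decides nothing. Over all 45 pairs the share met the bound set beforehand, so any pair of libraries stays a possible source of the pattern. Reads moved between transcripts that share sequence could also give it, and of 284 whole-count transcripts present in at least 8 libraries 0 showed the pattern, but only 0.0821 would be expected at the rate of the others, too few to decide. For these 11 transcripts, any pair of libraries, moved reads and a response to both targets cannot be told apart.

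Of the calls over all transcripts, the highest fitted rise in both contrasts with control belonged to 1 transcript. It held under 1 estimated count in either sgROSA library. It stood at 15.6 ± 4.23 CPM (SD, n = 5) in sgNFKBIZ and 23.0 ± 2.02 CPM (SD, n = 3) in sgPOU2F2 libraries.

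On the second principal component of whole-count transcripts, 20.3% of the variance, sgNFKBIZ_106 scored 2.93, the other 4 sgNFKBIZ libraries scored -8.64 to -1.73 and the sgROSA libraries scored 5.60 and 6.63.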
